A study of Rattus norvegicus with 9 samples.

How the data were processed

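Small RNA libraries of 9 samples of rat cornea were used, 3 each labelled as normal cornea, isograft and allograft. Per the labels, RNA was extracted with Trizol and libraries were made from 1 ug of total RNA with the Illumina TruSeq small RNA kit. The deposited table holds RPM values, read numbers scaled to a common library total, for 765 mature miRNAs in 9 columns, computed by the authors, and each column matched 1 library by its title, with 0 columns left unmatched. Per the submitters' processing notes, bcl2fastq, BWA and the rat genome build rn6 were used; their versions, the trimming, the miRNA annotation and the rule for reads that match several miRNAs are not given in the sources used here. Groups were taken from the tissue labels and the numbers 12, 34 and 56 from the titles, whose meaning the labels do not state.

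The RPM values moved in steps of a fixed size in each library, so whole reads could be recovered by dividing by the step. Of the values in each library, 100% came out whole within a tolerance of 0.1 read. The implied denominators ran from 11001459 to 12153889 reads, while the RPM columns summed to between 264393 and 655620, so the denominator also counted reads outside the listed miRNAs. What those reads are is not stated. RPM values therefore depend on how many other reads a library holds. A count of 3 reads corresponds to between 0.247 and 0.273 RPM. Shares of single libraries carry 95% exact binomial intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Pairs of libraries within a group differed far beyond counting noise (chi-square per degree of freedom 77.2 to 894), so none was treated as a duplicate.

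The filter, the model, the tests, the lists and the rule for naming miRNAs were chosen before the data were examined. miRNAs with at least 5 RPM in at least 3 libraries were kept, 281 of 765. Values were log2-transformed after adding a pseudocount of 1 RPM, so fold changes are on the log2(RPM + 1) scale and understate the change of low miRNAs. A moderated linear model with a mean-variance trend (limma 3.58.1 in R 4.3.3) was fitted to all 9 libraries at once, with 6 residual degrees of freedom and no covariate. Each pair of groups was compared, p-values were adjusted by the Benjamini-Hochberg method over the miRNAs kept, and the threshold was an adjusted p of 0.05. Exact two-sided permutation tests were used for single measures, where 3 libraries against 3 cannot give a p below 0.1.

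miRNAs were named by a rule: the 12 largest rises and the 12 largest falls of each comparison among miRNAs past the threshold, with a mean of at least 50 RPM in the higher group and no overlap between groups; the 10 most abundant miRNAs; and members of fixed lists. The 16 lists held 156 distinct miRNAs, of which 113 were kept. They covered leukocytes, inflammation-responsive miRNAs, red blood cells, the miR-200 family, corneal and squamous epithelium, stroma and fibroblasts, the miR-29 family, endothelium and vessel growth, proliferation-linked clusters, the let-7 family, muscle, neurons, lens with iris and retinal pigment epithelium, liver and plasma, the imprinted Dlk1-Dio3 cluster and hypoxia. The 14 lists with at least 3 kept members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. They were tested again with a correlation estimated from the data and with fry.

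The model was tested on simulated data with 60 changed miRNAs among 281 in each of 10 runs. It recovered 70.8%, 76.5% and 75.5% of 2-fold changes and 98.5%, 99.2% and 99.2% of 4-fold changes for isografts against normal corneas, allografts against normal corneas and allografts against isografts. Between 1.98% and 4.71% of its calls were false. A list of changed miRNAs was called in 10 of 10 runs and an unchanged list in 0. The simulated miRNAs varied independently of one another, and no library was shifted as a whole. These runs therefore cannot show how often a list of correlated members is called falsely. Nor do they give the share of false calls of single miRNAs where whole libraries shift together.

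Alternatives fixed beforehand were other pseudocounts, no filter or a filter at 50 RPM, scaling by the median of ratios, RPM without the most abundant miRNA, limma without the trend or with robust variance estimates, fits of only the groups compared, the number in the title as a block, and each library left out. On the recovered reads, edgeR 4.0.16 called 114, 193 and 163 miRNAs and DESeq2 1.42.0 called 119, 195 and 171, in the order isograft against normal, allograft against normal, allograft against isograft. Both tools scaled the libraries by factors of their own in place of RPM. Scaling to the sum of the listed miRNAs, a fit without isograft 12 and allograft 34, and miR-451-5p as a covariate for miR-122-5p were added after seeing the data. Neighbouring miRNA genes were taken from a gene table of the assembly GRCr8, which differs from the build of the reads, so it served for names and neighbours only.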

Results

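Small RNA was profiled by deep sequencing in corneas of Wistar rats labelled as 6 weeks of age. The series holds 3 libraries of normal cornea, 3 of isografts and 3 of allografts. By the meaning of these terms, donor and recipient are genetically matched in isografts and differ in allografts. The labels do not state the match itself, and the allografts are labelled Wistar like the other samples. Matched and differing donors are meant below by these names only. The series compares transplanted with untouched corneas, and grafts that differ by name in the genetic match of the donor. Donor strain, time after surgery and clinical state of the grafts were not stated in the labels. Libraries are named here by group and by the number in their title, 12, 34 or 56. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

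The table gives RPM, reads scaled to a common library total, for 765 mature miRNAs in 9 libraries, of which 159 were at 0 in every library and 281 were abundant enough to test. Each library had between 11001459 and 12153889 reads in its RPM denominator, and between 466 and 526 miRNAs were detected. Listed miRNAs held 57.6% ± 9.85 of the reads in normal corneas, 46.7% ± 9.03 in isografts and 35.6% ± 10.04 in allografts (SD, n = 3 each; exact permutation test over the 3 groups, two-sided p = 0.0786). The highest value was 65.6% in normal 34 (95% exact binomial interval 65.5 to 65.6) and the lowest 26.4% in allograft 34 (26.4 to 26.5). A single miRNA, miR-184, the most abundant miRNA of the corneal epithelium, took 28.9% ± 6.58 of the reads in normal corneas, 13.7% ± 0.620 in isografts and 4.15% ± 1.52 in allografts (exact permutation p = 0.00357). Without miR-184 the listed miRNAs held 28.8%, 33.0% and 31.4% of the reads (exact permutation p = 0.771).

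**Figure D1:**
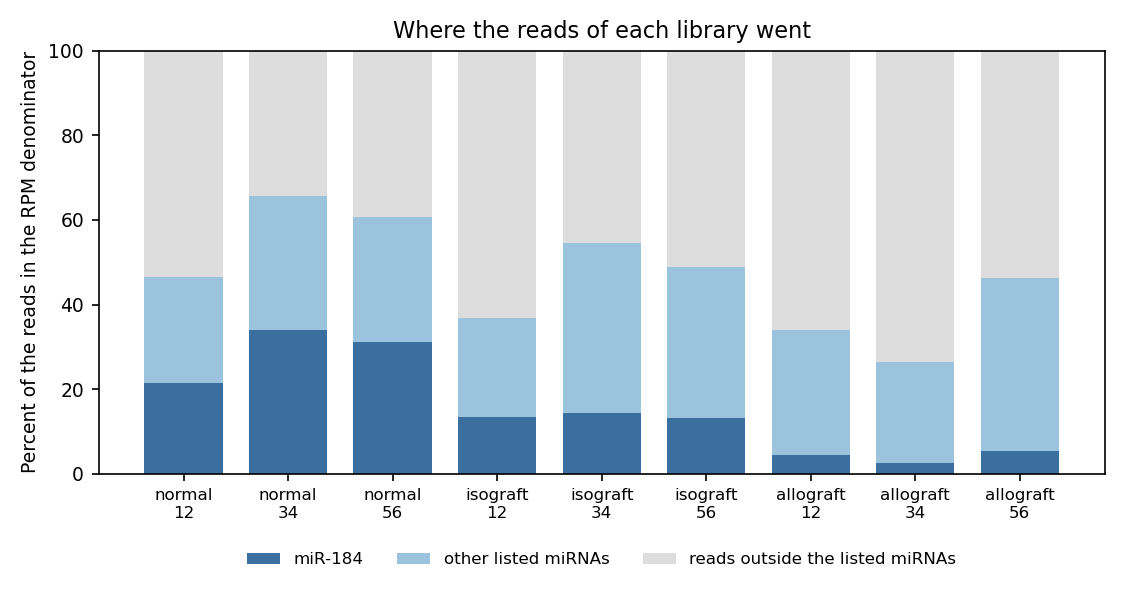
Percent of the reads in the RPM denominator that belonged to miR-184, to the other listed miRNAs and to no listed miRNA, in each of the 9 libraries. The miR-184 share lies between 21.4% and 33.98% in the normal corneas, between 13.2% and 14.4% in the isografts and between 2.48% and 5.45% in the allografts.

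After miR-184, the most abundant miRNAs were miR-21-5p, miR-148a-3p, miR-203a-3p, let-7i-5p, let-7f-5p, miR-26a-5p, miR-205, miR-27b-3p and let-7g-5p. The second place of miR-21-5p, a miRNA induced in inflammation and wound repair, came from the grafts, where its mean was 54475 RPM ± 22395 in isografts and 112073 ± 28849 in allografts, against 8258 ± 1569 in normal corneas. The first principal component carried 62.5% of the variance and placed the isografts between the normal corneas and the allografts. Within groups, libraries correlated across miRNAs at 0.992 to 0.994 in normal corneas, 0.976 to 0.993 in isografts and 0.976 to 0.992 in allografts. Between normal corneas and allografts the correlations ran from 0.848 to 0.882. Isograft 12 stood apart from the other isografts on the second component, which carried 19.0% of the variance, at 3.85 against -10.6 and -9.14, and on the third, at -11.7 against -3.17 and -2.51. A moderated F-test over the 3 groups (limma, Benjamini-Hochberg adjustment) found 147 of the 281 miRNAs to differ. Members of near-identical families (let-7, miR-10a and miR-10b, miR-17 with miR-20b, miR-29, miR-146a and miR-146b, miR-181, miR-200b with miR-429) can share reads, so the split between such members is uncertain.

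Isografts were compared with normal corneas to see what transplantation changed where the donor was matched. Single miRNAs are ranked here among those past the threshold with a mean of at least 50 RPM in the higher group and no overlap between groups. miRNAs of stromal, smooth muscle and vascular cells were the most frequent among the 12 largest rises. miR-10a-5p rose from 12.6 RPM ± 4.38 to 196 ± 68.0 (log2 fold change 3.85, SE 0.40, adjusted p = 3.7e-08, n = 3 per group), and miR-10b-5p, from the other Hox cluster copy of this family, rose by 3.55 (SE 0.37). miR-143 and miR-145, made from 1 precursor transcript in fibroblasts and smooth muscle, rose by 3.15 (SE 0.37) for miR-143-3p, 3.40 (SE 0.43) for miR-143-5p, 3.18 (SE 0.41) for miR-145-5p and 2.90 (SE 0.42) for miR-145-3p. The endothelial miR-126a-3p rose by 3.16 (SE 0.41) and miR-126a-5p by 2.92 (SE 0.51), and the myeloid miR-223-3p rose by 3.35 (SE 0.41). The others of these 12 were miR-224-5p at 3.12 (SE 0.39), miR-21-5p at 2.64 (SE 0.34) and miR-351-5p at 2.55 (SE 0.41).

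Falls in isografts were fewer and smaller. Within the limits of abundance and overlap 6 miRNAs fell; miR-451-5p, with overlap between groups, is given below. miR-1b, of the muscle miR-1 family, fell by 1.78 on the log2 scale (SE 0.38, adjusted p = 0.00054), from 230 RPM ± 40.3 to 67.9 ± 20.6. miR-1-3p of that family was too low to test, at 0.73, 0.45 and 0.82 RPM in normal corneas. In isografts miR-1-3p was at 1.89, 1.18 and 1.36 RPM, so it did not fall with miR-1b. The epithelial miRNAs miR-200a-3p, miR-205, miR-200b-3p and miR-184 and the pigment epithelium and lens miRNA miR-204-5p had log2 fold changes of -1.25 (SE 0.42), -1.17 (SE 0.39), -1.08 (SE 0.35), -1.05 (SE 0.32) and -1.11 (SE 0.37), with adjusted p between 0.015 and 0.031.

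The stroma and fibroblast list had the largest shift in isografts, with a median log2 fold change of 2.90. Of its 11 tested members 8 rose, with the same 8 when adjusted over the list alone, among them miR-214-3p at 2.19 (SE 0.41) and miR-199a-5p at 1.17 (SE 0.38), while miR-152-3p at 0.43 (SE 0.35) did not pass (camera, adjusted p = 1.2e-07; adjusted p = 0.476 with an estimated correlation). In the leukocyte list, miRNAs enriched or induced in white blood cells, 8 of 11 rose (8 adjusted over the list alone), with a median of 2.31 (adjusted p = 3.5e-05; adjusted p = 0.489 with an estimated correlation). They included miR-142-3p, found throughout blood cell lineages, at 2.91 (SE 0.45), the activation-induced miR-155-5p at 2.51 (SE 0.39) and the lymphocyte miR-150-5p at 1.34 (SE 0.39), while miR-181a-5p stood at -0.48 (SE 0.38, not past the threshold). In the inflammation-responsive list 7 of 11 rose (7 adjusted over the list alone), with miR-132-3p at 2.84 (SE 0.36), miR-146a-5p at 2.09 (SE 0.36) and miR-146b-5p at 1.62 (SE 0.34) (adjusted p = 0.00059; adjusted p = 0.554 with an estimated correlation). This list shares miR-21-5p, miR-146a-5p, miR-155-5p and miR-223-3p with the leukocyte list. The endothelium and vessel growth list had 6 of 11 members higher (6 adjusted over the list alone), with miR-322-5p at 2.28 (SE 0.45) and miR-503-5p at 1.33 (SE 0.48) beside the miR-126a arms (adjusted p = 0.0041; adjusted p = 0.554 with an estimated correlation).

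The miR-200 family, which keeps epithelial cells in their epithelial state, was lower as a list, with a median of -0.83, while 2 of its 7 tested members, miR-200a-3p and miR-200b-3p, fell singly (2 adjusted over the list alone; adjusted p = 0.0049; adjusted p = 0.554 with an estimated correlation). The list of lens, iris and retinal pigment epithelium had 2 of 6 members lower, miR-204-5p and miR-184 (2 adjusted over the list alone; adjusted p = 0.044; adjusted p = 0.572 with an estimated correlation), and passed in 12 of 18 other settings. The other 8 lists tested did not pass. Their medians were -0.41 for corneal and squamous epithelium (adjusted p = 0.051), -0.90 for liver and plasma (0.051), -0.80 for muscle (0.067), -0.13 for the imprinted Dlk1-Dio3 cluster (0.069), -0.42 for miR-29 (0.385), 0.23 for neuron (0.471), -0.02 for proliferation-linked clusters (0.641) and 0.30 for let-7 (0.677). The lists of corneal and squamous epithelium, liver and plasma, and the Dlk1-Dio3 cluster passed in 8, 9 and 4 of 18 other settings. The medians of the Dlk1-Dio3, neuron and proliferation-linked lists change sign under 1 of 3 other scalings, and the mean of the neuron list, at -0.13, and of the proliferation-linked list, at 0.08, had the other sign than its median. Single members past the threshold within the 8 lists were miR-184 and miR-205 in the epithelium list, miR-133a-3p at -1.55 (SE 0.37) in muscle, miR-138-5p at -1.76 (SE 0.36) in neuron and miR-381-3p at -1.19 (SE 0.35) in the Dlk1-Dio3 cluster.

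In all, 60 of 281 miRNAs changed in isografts, 47 higher and 13 lower (limma on log2(RPM + 1), Benjamini-Hochberg adjustment over the miRNAs tested). Of the 281, 94 had no overlap between the 3 isograft and the 3 normal libraries, 33.5% where chance gives 10%. Scaling by the median of ratios called 114, 67 higher and 47 lower, and RPM without miR-184 called 60, 38 higher and 22 lower. These scalings and that to the sum of the listed miRNAs moved the median log2 fold change of all miRNAs from 0.05 to -0.04, -0.22 and 0.35 and turned the median of no list called here. The 5 small falls named above (miR-200a-3p, miR-205, miR-204-5p, miR-200b-3p and miR-184) were not past the threshold in 3 to 5 of 23 other settings each.

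Allografts were compared with normal corneas to see what transplantation changed where the donor differed. Within the same limits leukocyte miRNAs were the most frequent among the 12 largest rises. miR-142-3p rose from 2.82 RPM ± 1.18 to 525 ± 124 (log2 fold change 7.13, SE 0.45, adjusted p = 3.2e-13, n = 3 per group) and miR-142-5p by 6.30 (SE 0.42). miR-223-3p rose by 5.60 (SE 0.41), miR-155-5p by 5.43 (SE 0.39) and miR-150-5p by 5.23 (SE 0.39), the last from 29.9 RPM ± 2.90 to 1224 ± 520. miR-363-3p, of a cluster related to miR-17-92, rose by 5.58 (SE 0.40) from 2.06 RPM ± 0.139 to 149 ± 43.0. miR-146a-5p and miR-146b-5p, which are induced by NF-kB signalling, rose by 3.88 (SE 0.36) and 3.61 (SE 0.34), and miR-21-5p rose by 3.75 (SE 0.34). miR-10a-5p at 3.45 (SE 0.40), miR-126a-5p at 3.29 (SE 0.51) and miR-10b-5p at 3.04 (SE 0.37) completed the 12; rises of similar size below 50 RPM included miR-223-5p at 4.48 (SE 0.36) and, given below, miR-21-3p and miR-147.

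Within the same limits, which left out miR-122-5p and miR-451-5p for overlap, miR-1b fell most. It fell by 3.23 on the log2 scale (SE 0.38, adjusted p = 3.7e-08) to 23.4 RPM ± 1.32. miR-184 fell by 2.85 (SE 0.32), from 288696 RPM ± 65850 to 41540 ± 15232, miR-200b-3p fell by 2.71 (SE 0.35), miR-204-5p fell by 2.47 (SE 0.37) and the keratinocyte miRNA miR-205 fell by 2.06 (SE 0.39). The other miR-200 members among the 12 largest falls were miR-200b-5p at -2.34 (SE 0.43), miR-200a-3p at -2.13 (SE 0.42), miR-429 at -1.87 (SE 0.43) and miR-200a-5p at -1.72 (SE 0.37). miR-31a-5p fell by 1.85 (SE 0.43), miR-182, of a sensory and epithelial cluster, fell by 1.78 (SE 0.34), and miR-127-3p, of the imprinted Dlk1-Dio3 cluster, fell by 1.65 (SE 0.34).

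By list, 9 of 11 leukocyte miRNAs rose in allografts (9 adjusted over the list alone), with a median of 4.48, leaving miR-181a-5p at -0.47 (SE 0.38) and miR-181b-5p at -0.39 (SE 0.38) short of the threshold (camera, adjusted p = 6.5e-08; adjusted p = 0.489 with an estimated correlation). In the inflammation-responsive list 8 of 11 rose, including miR-21-3p at 3.39 (SE 0.36) and miR-147 at 3.36 (SE 0.39), and the epithelial members miR-31a-5p and miR-203a-3p fell (8 and 2 adjusted over the list alone; adjusted p = 0.00014; adjusted p = 0.489 with an estimated correlation). The stroma list rose with a median of 1.83, 7 of 11 members past the threshold (7 adjusted over the list alone), from miR-10a-5p at 3.45 (SE 0.40) to miR-214-3p at 1.19 (SE 0.41), while miR-199a-3p stood at -0.20 (SE 0.37) (adjusted p = 0.012; adjusted p = 0.489 with an estimated correlation). The proliferation-linked clusters, which hold the miR-17-92 genes, rose with a median of 1.01, 5 of 11 members past the threshold (5 adjusted over the list alone), led by miR-18a-5p at 2.73 (SE 0.35) and miR-19a-3p at 1.95 (SE 0.39) (adjusted p = 0.037; adjusted p = 0.645 with an estimated correlation). That call held in 8 of 18 other settings.

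Of the lists, 4 were lower. In the miR-200 family 6 of 7 fell (6 adjusted over the list alone), with a median of -1.87 (adjusted p = 0.0016; adjusted p = 0.489 with an estimated correlation), miR-141-3p being the exception at -0.91 (SE 0.45). In the list of corneal and squamous epithelium 7 of 10 fell (7 adjusted over the list alone), with a median of -1.50, among them miR-203a-3p at -1.40 (SE 0.38) and miR-183-5p at -1.46 (SE 0.35) (adjusted p = 0.0028; adjusted p = 0.489 with an estimated correlation). All 6 members tested for lens, iris and retinal pigment epithelium fell (6 adjusted over the list alone), including miR-211-5p at -1.64 (SE 0.40) and, shared with the corneal list, miR-184 and the miR-183 cluster (adjusted p = 0.0014; adjusted p = 0.489 with an estimated correlation). The Dlk1-Dio3 cluster, imprinted miRNA genes expressed from the maternal chromosome, had 16 of 22 members lower and none higher (20 lower adjusted over the list alone), with a median of -1.31, from miR-382-5p at -1.70 (SE 0.39) to miR-433-3p at -0.70 (SE 0.35, not past the threshold) (adjusted p = 4.6e-05; adjusted p = 0.489 with an estimated correlation).

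The other 6 lists tested did not pass in allografts against normal corneas. Endothelium and vessel growth had a median of 0.61 (adjusted p = 0.095), with 5 members higher, among them miR-126a-3p at 3.03 (SE 0.41) and miR-322-5p at 2.38 (SE 0.45), and miR-130a-3p lower at -0.99 (SE 0.41). Medians were -1.26 for liver and plasma (adjusted p = 0.092), -1.34 for muscle (0.225), -0.37 for let-7 (0.281), -0.17 for miR-29 (0.963) and -0.13 for neuron (0.963). The let-7, miR-29 and neuron medians change sign under 1 of 3 other scalings, and the means of the miR-29 list (0.13) and the neuron list (0.09) had the other sign than their medians. In the neuron list miR-7a-5p, also made in endocrine cells, rose by 2.13 (SE 0.33) and miR-138-5p fell by 1.78 (SE 0.36). Also past the threshold were let-7b-5p at -0.94 (SE 0.35), let-7c-5p at -1.01 (SE 0.33), miR-29b-3p at 1.06 (SE 0.39), and in muscle miR-133a-3p at -1.34 (SE 0.37) and miR-499-5p at -1.42 (SE 0.45). In the liver and plasma list miR-192-5p at -1.28 (SE 0.36), miR-194-5p at -1.24 (SE 0.44) and miR-122-5p at -3.48 (SE 0.90) were past the threshold. The spread of miR-122-5p within groups was 2.20 on the log2 scale against a median of 0.447 over all miRNAs, and with robust variance estimates its difference was not past the threshold (SE 1.74, adjusted p = 0.153, in a range from 3.6e-39 to 0.291 over 24 alternatives, 7 of them not past it).

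Red blood cell miRNAs varied widely within groups. miR-451-5p was at 121, 31.9 and 141 RPM in the normal corneas, at 69.5, 3.00 and 5.91 RPM in the isografts and at 3.82, 120 and 3.27 RPM in the allografts. Its log2 fold change was -2.73 (SE 0.88, adjusted p = 0.025) in isografts and -2.61 (SE 0.88, adjusted p = 0.016) in allografts against normal corneas, and with robust variance estimates neither was past the threshold (adjusted p = 0.392 and adjusted p = 0.262, in ranges from 8.1e-27 to 0.460 and from 3.5e-30 to 0.673 over 22 alternatives). miR-486 followed the same libraries, with 946 RPM in allograft 34 against 15.3 and 13.8 in the other allografts. Only these 2 members of the red blood cell list were abundant enough, too few for a list test. The same held for the hypoxia list, of which miR-210-3p alone was tested, at -0.10 (SE 0.41) in isografts and -0.51 (SE 0.41) in allografts.

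In all, 133 of 281 miRNAs changed in allografts against normal corneas, 65 higher and 68 lower, and 169 of the 281 had no overlap between the groups (60.1%, chance 10%). The split depended on the scaling: scaled to the sum of the listed miRNAs it was 141 higher and 44 lower, and with RPM without miR-184 it was 51 higher and 104 lower. The median log2 fold change of all miRNAs moved from -0.14 to 0.55 and to -0.56, and the median of no list called here changed sign.

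**Figure D2:**
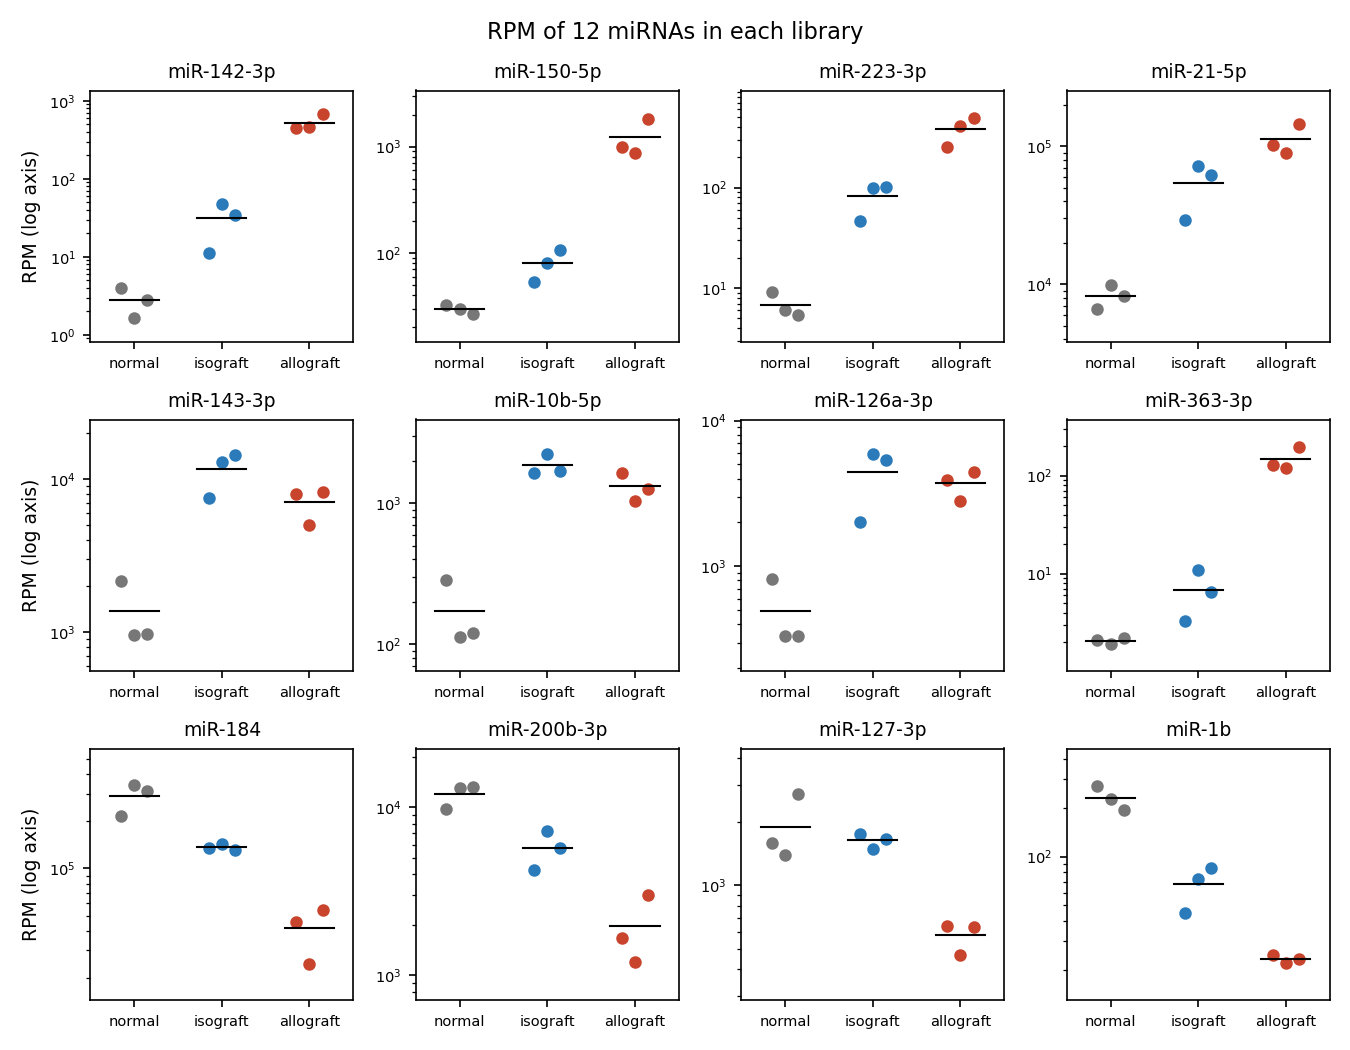
RPM of 12 miRNAs in each of the 9 libraries, on a log axis; each point is 1 library and each line the mean of a group of 3. miR-142-3p, miR-150-5p, miR-223-3p and miR-363-3p step up from normal corneas to isografts to allografts, miR-143-3p and miR-10b-5p are highest on average in isografts, and miR-184, miR-200b-3p and miR-1b step down.

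Changes against normal corneas went the same way in both grafts for all miRNAs past the threshold in both: 39 were higher, 12 were lower and 0 went opposite ways (limma; also 0 at an unadjusted p under 0.05). edgeR and DESeq2 on recovered reads each gave 2, miR-130b-5p and miR-181a-1-3p, lower in isografts and higher in allografts and named after their values were seen. Simulations without any effect, with all 9 libraries drawn anew and 3 normal libraries shared, gave means of 0.03 and 0.02 shared calls. Such runs hold hardly any calls, so they do not measure what shared controls add where effects exist. Independent lists of these sizes would share 10.9 and 3.15. The log2 fold changes of both grafts correlated across miRNAs at 0.76, against a simulated mean of 0.42 and 95th percentile of 0.92, so that value lay within what shared controls gave without any effect, and their covariance was 1.32 against 0.0489. Part of the excess in shared calls may come from the shared controls, since 3 controls are too few to split. The leukocyte members miR-142-3p, miR-150-5p and miR-155-5p lay among the 18 miRNAs that were higher in both grafts and higher in allografts than in isografts. The 4 that were higher in both grafts and lower in allografts than in isografts were miR-145-5p, miR-224-5p, miR-452-5p and miR-504, the last 2 named after their values were seen. Past the threshold in allografts alone were 26 higher and 56 lower, and 51 of these 82 also differed between allografts and isografts.

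**Figure D3:**
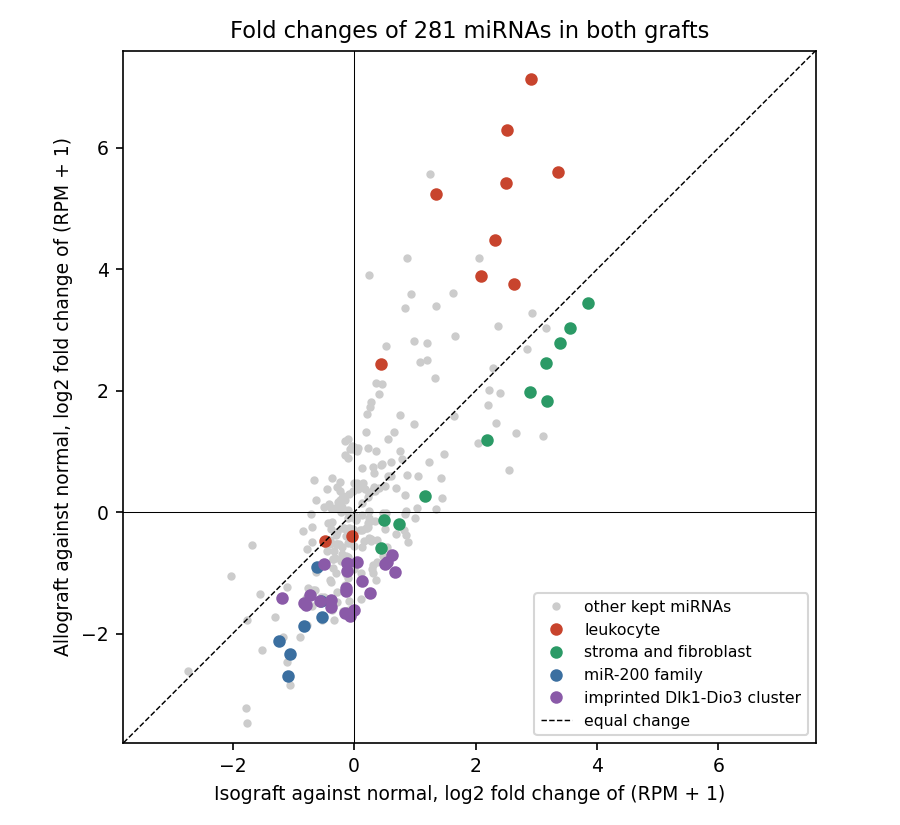
Log2 fold change of (RPM + 1) against normal corneas for 281 miRNAs, isografts on the horizontal and allografts on the vertical axis, with 4 miRNA lists in colour and a dashed line of equal change. Leukocyte miRNAs past the threshold lie above the line (miR-142-3p at 2.91 and 7.13) and stromal miRNAs below it (miR-145-5p at 3.18 and 1.83).

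Allografts were compared with isografts to see how grafts of an unmatched donor differed from those of a matched donor. Within the same limits, leukocyte miRNAs were prominent among the 12 largest rises. miR-142-3p rose from 31.2 RPM ± 18.4 in isografts to 525 ± 124 in allografts (log2 fold change 4.22, SE 0.45, adjusted p = 2.2e-08, n = 3 per group), miR-150-5p by 3.89 (SE 0.39), miR-142-5p by 3.78 (SE 0.42), miR-155-5p by 2.92 (SE 0.39), miR-223-3p by 2.24 (SE 0.41) and miR-342-3p, enriched in lymphocytes, by 2.01 (SE 0.38). The largest rise was that of miR-363-3p, at 4.34 (SE 0.40), from 6.85 RPM ± 3.78 to 149 ± 43.0. miR-146b-5p rose by 1.99 (SE 0.34), miR-146a-5p by 1.79 (SE 0.36), miR-7a-5p by 1.77 (SE 0.33), miR-340-5p by 1.66 (SE 0.41) and miR-532-5p by 1.39 (SE 0.38).

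Among the falls were miRNAs that were higher in isografts than in normal corneas and miRNAs of the epithelium. miR-224-5p, at 66.7 RPM ± 5.57 in isografts and 18.4 ± 6.86 in allografts, fell by 1.86 (SE 0.39, adjusted p = 0.00065) and miR-351-5p fell by 1.85 (SE 0.41); both had risen in isografts against normal corneas. miR-184 fell by 1.79 (SE 0.32, adjusted p = 8.6e-05), from 136818 RPM ± 6200 to 41540 ± 15232. miR-200b-3p fell by 1.62 (SE 0.35), miR-182 fell by 1.45 (SE 0.34), miR-183-5p fell by 1.38 (SE 0.35) and miR-1b fell by 1.45 (SE 0.38). miR-541-5p and miR-127-3p of the Dlk1-Dio3 cluster fell by 1.60 (SE 0.39) and fell by 1.496 (SE 0.34). miR-125a-5p fell by 1.53 (SE 0.37), miR-676 fell by 1.47 (SE 0.39) and miR-145-5p fell by 1.35 (SE 0.41). miR-676 lost its call in 1 of 23 other settings and miR-145-5p in 3.

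By list, 9 of 11 leukocyte miRNAs rose from isografts to allografts (9 adjusted over the list alone), with a median of 2.16, again without miR-181a-5p at 0.01 (SE 0.38) and miR-181b-5p at -0.35 (SE 0.38) (camera, adjusted p = 1.1e-08; adjusted p = 0.711 with an estimated correlation). Of the red blood cell miRNAs, miR-451-5p stood at 0.12 (SE 0.88) and miR-486 at 0.99 (SE 0.94), neither past the threshold and both with wide errors. In the inflammation-responsive list 7 of 11 rose, with miR-147 at 2.52 (SE 0.39) and miR-21-3p at 2.05 (SE 0.36), and miR-132-3p stood at -0.16 (SE 0.36) (7 higher and 2 lower adjusted over the list alone; adjusted p = 0.0013; adjusted p = 0.711 with an estimated correlation). The proliferation-linked clusters had 5 of 11 members higher (7 adjusted over the list alone), with miR-18a-5p at 2.21 (SE 0.35), miR-17-5p at 1.13 (SE 0.41) and miR-16-5p at 1.06 (SE 0.40) (adjusted p = 0.0013; adjusted p = 0.711 with an estimated correlation).

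The Dlk1-Dio3 cluster had 13 of 22 members lower and none higher (15 lower adjusted over the list alone), with a median of -1.14, among them miR-409a-3p at -1.66 (SE 0.39), miR-382-5p at -1.64 (SE 0.39) and miR-370-3p at -1.58 (SE 0.36) (adjusted p = 0.00012; adjusted p = 0.711 with an estimated correlation). In the list of lens, iris and retinal pigment epithelium 5 of 6 fell, including miR-204-5p at -1.36 (SE 0.37) and miR-211-5p at -1.44 (SE 0.40) (6 adjusted over the list alone; adjusted p = 0.0053; adjusted p = 0.711 with an estimated correlation). In the corneal and squamous epithelium list 3 of 10 fell, miR-184, miR-182 and miR-183-5p (7 adjusted over the list alone; adjusted p = 0.012; adjusted p = 0.711 with an estimated correlation). In the miR-200 family 4 of 7 fell, with a median of -1.03 (5 adjusted over the list alone; adjusted p = 0.045; adjusted p = 0.711 with an estimated correlation), and in the stroma list 3 of 11 fell, miR-145-5p, miR-152-3p and miR-199a-3p, with a median of -0.90 (2 adjusted over the list alone; adjusted p = 0.045; adjusted p = 0.711 with an estimated correlation). The miR-200 call held in 12 and the stroma call in 10 of 18 other settings.

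The other 6 lists tested did not pass between the grafts. The let-7 list had a median of -0.56 (adjusted p = 0.089), with let-7c-5p at -1.32 (SE 0.33), let-7b-5p at -1.23 (SE 0.35) and let-7e-5p at -1.20 (SE 0.36) past the threshold. Endothelium and vessel growth had a median of -0.26 (adjusted p = 0.618), with miR-23b-3p past the threshold at -1.05 (SE 0.34) and miR-126a-3p at -0.13 (SE 0.41). Medians were 0.25 for miR-29 (adjusted p = 0.440), -0.45 for liver and plasma (0.570), -0.02 for neuron (0.513) and -0.09 for muscle (0.994). The endothelium, neuron and muscle medians change sign under 1 or 2 of 3 other scalings, and the mean of the neuron list was 0.22.

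In all, 97 of 281 miRNAs differed between allografts and isografts, 38 higher and 59 lower in allografts, and 109 of the 281 had no overlap (38.8%, chance 10%). Scaling by the median of ratios called 169, 80 higher and 89 lower, and scaled to the sum of the listed miRNAs the split was 85 higher and 55 lower. The median log2 fold change of all miRNAs moved from -0.29 to -0.09 and to 0.10, and the median of no list called here changed sign. Single libraries moved the count, to 147 (33 higher and 114 lower) without isograft 12 and to 52 (32 higher and 20 lower) without allograft 34; without both, a choice made after seeing the data, it was 124, 36 higher and 88 lower.

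**Figure D4:**
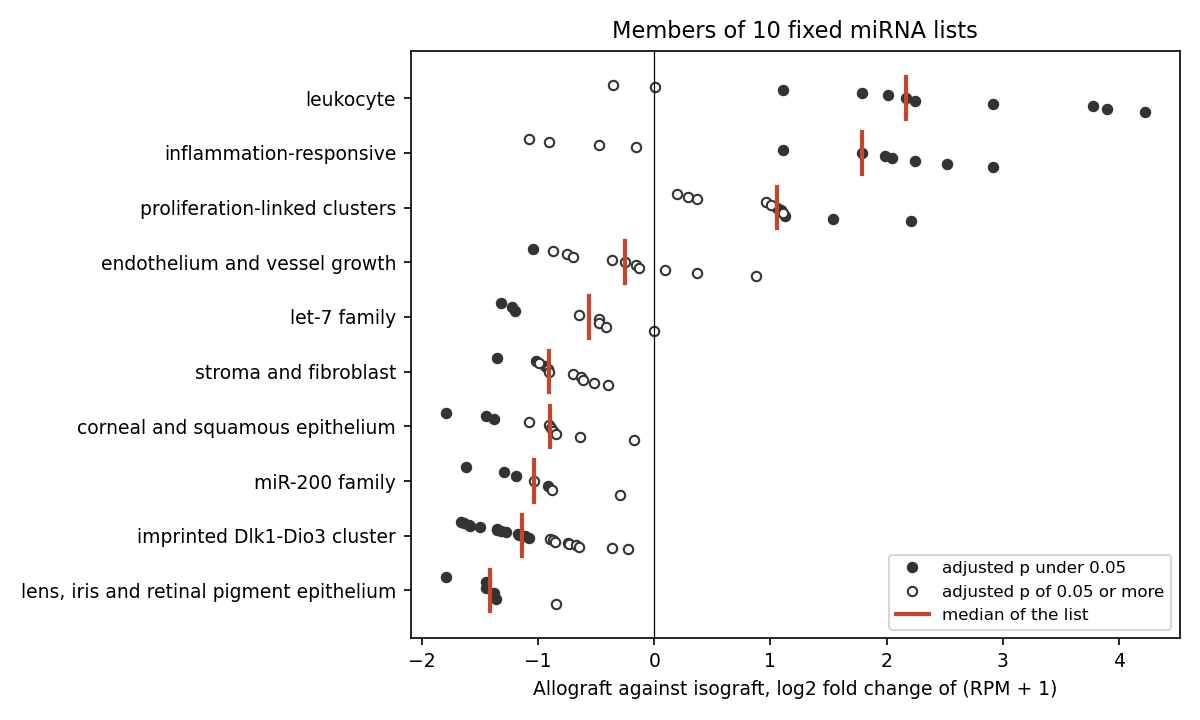
Log2 fold change of (RPM + 1), allograft against isograft, for the members of 10 fixed miRNA lists; filled points are past adjusted p 0.05 and the vertical bar is the median of the list. The medians run from 2.16 in the leukocyte list to -1.41 in the list of lens, iris and retinal pigment epithelium; the endothelium median of -0.26 changes sign under 1 of 3 other scalings.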

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

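The tests of blood, of equal dilution and of the RPM denominator for the falling lists were chosen only after the results were seen. So were the test of carried-over blood for miR-122-5p, the split counts under median-of-ratios scaling and the miRNAs read with robust variance estimates. The robust estimates themselves were among the alternatives fixed beforehand.

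Reads outside the listed miRNAs, the rest of the reads beside the listed share, entered no comparison of miRNAs and had higher means in both grafts than in the control corneas. They made up 64.4% of the denominator in allografts and 53.3% in isografts, against 42.4% in normal corneas, by the mean of 3 libraries each (exact permutation test over the 3 groups, two-sided p = 0.0786). The exact permutation tests of pairs of groups gave p = 0.1 for allografts against normal corneas, the smallest that 3 libraries against 3 can give, p = 0.3 for isografts against normal corneas and p = 0.2 for allografts against isografts. The difference went with the share of miR-184, which was 28.9% in normal corneas and 4.15% in allografts, while the other listed miRNAs held 28.8%, 33.0% and 31.4% in normal corneas, isografts and allografts (exact permutation p = 0.771).

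With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split of isografts and normal corneas gave 60 miRNAs and the highest other 0 (1 of 10 splits as large); for allografts and normal corneas it gave 133 and 0 (1 of 10). For allografts and isografts it gave 97, and another split gave 104 (2 of 10). That split set isograft 12, allograft 12 and allograft 34 against the other libraries, and so parted libraries with 36.8%, 33.9% and 26.4% of reads in listed miRNAs from those with 54.5%, 48.8% and 46.3%, which points to a structure of the libraries; under median-of-ratios scaling it gave 0 and the real split 169. For counts of lists the real split gave 6 against a highest other of 9 in isografts and normal corneas (4 of 10 splits), 8 against 9 in allografts and normal corneas (4 of 10) and 8 against 7 between the grafts (1 of 10).

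Over all 9 libraries, 100 splits were drawn. For the F-test over 3 groups 2 of 100 gave as many miRNAs, the real 147 and a split with 150 that kept the normal corneas apart and parted the grafts by the same shares; under median-of-ratios scaling that split gave 87, the real one 221 and the highest other 120. For miRNAs changed in both grafts the real split gave 51 and the highest other 32 (1 of 100). For both counts the share was under 0.05, which argues against a random grouping of these 9 libraries. The labels do not say that the libraries came from separate animals, so chance differences between animals are not excluded.

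The leukocyte list was higher in allografts than in isografts, with white blood cells in the graft or induction in resident cells as untested biological explanations. For the RPM denominator, the lowest median over 3 scalings was 2.16, that of RPM itself, where 0.5 or less was needed. Both other scalings moved allograft values up against isografts, the stroma list mean from -0.82 to -0.41 and -0.60. The limit of 0.5 could therefore not be reached, and the test could not decide. The values show only that neither of these scalings lowers the rise. The first test did not decide on blood left in the tissue. The rise of miR-142-3p exceeded that of miR-451-5p by 4.10 with a standard error of 2.51, less than the 2 standard errors set as the limit. After that result, further readings were tried: without allograft 34, the allograft with the most miR-451-5p, the list median was 2.17 and miR-451-5p stood at -1.46. Blood of the composition of a normal cornea could give at most 0.364%, 13.1% and 0.170% of the median leukocyte miRNA in allografts 12, 34 and 56. The value for allograft 34 was over the limit of 10% set for this reading, so blood stays open for that library. For allografts 12 and 56 the values argue against blood of this composition as the main source. The reading rests on an assumed profile, so blood of another composition is not excluded.

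The miR-200, epithelium, stroma and Dlk1-Dio3 lists were lower in allografts than in isografts. An equal dilution of tissue cells by added cells may account for these 4, but they were grouped because they fell in these data, so their likeness is weak support. The others departed from the mean of the stroma list by at most -0.27 (SE 0.24). Of 50 members 0 departed from the common fall in limma after adjustment. At an unadjusted p under 0.05, 11 did, more than chance alone would give among independent members. Members ranged from miR-184 at -0.79 to miR-24-3p at 0.82. The list of lens, iris and retinal pigment epithelium departed by -0.56 (SE 0.22), and by -0.59 (SE 0.23) over the 2 members not shared with the epithelium list. Both passed the limit of 2 standard errors, which argues against equal dilution for this list, though weakly with 3 libraries per group. Its other members are in the epithelium list, which departed by -0.19 (SE 0.15). The endothelium list departed the other way, by 0.55 (SE 0.17), also beyond 2 standard errors, which argues against an equal dilution that covers this list. The RPM denominator as the whole cause was argued against, since under both other scalings the 4 list means stayed below 0 by more than 2 standard errors, from -0.41 (SE 0.15) to -0.89 (SE 0.19), the miR-200 family at -0.63 (SE 0.26) being nearest to that limit; a limit first set for RPM as well, missed by that family at -1.03 (SE 0.52), was dropped because the spread under RPM holds that of the denominator. Against normal corneas the lists parted from stroma by -2.43 to -3.34 in the grafts, so a single dilution cannot describe the step from normal cornea to graft, and loss of tissue cells or lower expression within them stays open and untested.

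miR-122-5p, a liver miRNA found in plasma, was lower in allografts than in normal corneas by -3.48 on the log2 scale. Its call, past the threshold at -3.48 (SE 0.90), depended on 1 library: without normal 56 the difference was -3.07 (SE 1.21, adjusted p = 0.0565, in a range from 3.6e-39 to 0.291 over 24 alternatives), while its size with 1 library left out stayed between -2.78 and -4.81. Carried-over blood cannot be told apart from other explanations with so few libraries: within groups it followed miR-451-5p with r = 0.73 (exact permutation two-sided p = 0.106; Spearman's rho 0.63, p = 0.199; r = 0.32 without allograft 34 and isograft 12, so the relation rests on these libraries). With miR-451-5p as a covariate the difference shrank to -1.50 (SE 1.18, adjusted p = 0.291, 43.1% of its size). The residual SDs of miR-486, miR-122-5p and miR-451-5p were the 3 highest (2.30, 2.20 and 2.14), so their limma standard errors were pulled far towards the trend.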

How the results depend on the processing

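Scaling to the sum of the listed miRNAs and the fit without isograft 12 and allograft 34 were chosen only after the results were seen. The filter at 50 RPM tested fewer miRNAs and gave 30 for isograft against normal, 63 for allograft against normal, 44 for allograft against isograft, 68 in the F-test and 25 in both grafts. Median-of-ratios scaling gave 114, 169, 221 and 91 for isograft against normal, allograft against isograft, the F-test and both grafts. For the first 2 of these, edgeR on recovered reads gave 114 and 163 and DESeq2 119 and 171. Scaling to the sum of the listed miRNAs gave 120 for isograft against normal and 101 in both grafts. These settings all replaced the RPM scaling, and median-of-ratios scaling came close to edgeR and DESeq2 without a count model. The cause was not tested further. Leaving out 1 library moved allograft against isograft from 52 (without allograft 34) to 147 (without isograft 12), with fewer samples in each fit. Without both libraries the counts were 87, 153 and 124. In the fits without isograft 12, without isograft 56, without both libraries and with the block, limma estimated an infinite prior, so single noisy miRNAs there take the variance of the trend. With an estimated correlation between members 0, 0 and 0 lists passed (camera), against 5, 9 and 3 with fry. Between the grafts, the inflammation-responsive (fry, adjusted p = 0.052), epithelium (0.070), miR-200, stroma and proliferation-linked lists (0.082 each) did not pass fry. Against normal corneas, miR-200 (0.202) and lens (0.224) in isografts and the proliferation-linked list (0.063) in allografts did not pass it. Fry added liver and plasma in both grafts and muscle in allografts. Under scaling to the sum of the listed miRNAs, allograft against normal, 8 miRNAs not past the threshold by RPM turned higher: let-7i-5p 0.58, let-7f-5p 0.46, miR-9a-5p 0.46, miR-24-3p 0.67, miR-218a-5p 0.58, miR-23b-3p 0.36, let-7d-5p 0.55 and miR-378a-3p 0.46; the scaling raised the median of all miRNAs to 0.55. The replicate block, the number in the title, gave 66, 143 and 112. Libraries of the same number had correlations from -0.51 to 0.56 in their deviations from group means. Those of different numbers had correlations from -0.72 to 0.60. With 3 libraries per group these ranges cannot decide whether the numbers pair the samples. Calls were counted once per miRNA or list, comparison and setting, and unchanged entries include those without a call. Among named and listed miRNAs, 104 calls were lost, 386 gained and 4554 entries unchanged over the other settings. With 1 library left out, 167 were lost, 99 gained and 3055 unchanged. Of list calls, 40 were lost, 19 gained and 397 entries unchanged over the other settings. With 1 library left out, 20 were lost, 9 gained and 349 unchanged. The estimated correlation alone lost all 6, 8 and 8 list calls. No call made by RPM turned to the other direction. The correlation of the grafts' fold changes stayed between 0.73 and 0.80. Floors of 0.247 to 0.273 RPM limit what can be said of miRNAs near 0 in normal corneas.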

Other observations

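The tests of neighbouring genes were written before their results were seen. Those miRNAs in this paragraph and the next that the naming rule did not give were chosen after their values were seen. miR-20b-5p, which lies in the same cluster as miR-363-3p, went from 1.24 RPM ± 0.896 in normal corneas and 3.17 ± 1.68 in isografts to 38.6 ± 10.3 in allografts (SD, n = 3 each), a log2 fold change of 3.32 (SE 0.39) against isografts by limma, and miR-17-2-3p changed by 3.66 (SE 0.35). Of their relatives, miR-18a-5p at 2.21, miR-19a-3p at 1.54 and miR-17-5p at 1.13 were past the threshold against isografts. miR-93-5p at 0.29 (SE 0.41), miR-25-3p at 0.20 (SE 0.35) and miR-106b-5p at 0.96 (SE 0.46) were not past it. miR-511-3p, made from the gene of the macrophage mannose receptor, rose in isografts by 2.06 (SE 0.39) and in allografts by 4.19 (SE 0.39) against normal corneas.

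Several miRNAs were raised in isografts and lower again in allografts. miR-452-5p, which shares a host gene with miR-224-5p, stood at 0.424 RPM ± 0.105, 8.16 ± 1.87 and 2.67 ± 1.31 in normal corneas, isografts and allografts. miR-455-3p and miR-503-3p rose in isografts by 1.44 (SE 0.40) and 1.36 (SE 0.39) and differed in allografts from isografts by -1.21 (SE 0.40) and -1.31 (SE 0.39). miR-34c-5p, of a family induced by p53, rose alike in both grafts, by 2.22 (SE 0.41) and 2.02 (SE 0.41), and so did its neighbour miR-34b-3p at 1.64 (SE 0.35) and 1.59 (SE 0.35). Of the neighbours of miR-532-5p, miR-501-3p at 1.25 (SE 0.34) and miR-362-3p at 1.47 (SE 0.42) were higher in allografts than in isografts, and miR-362-5p at 0.998 (SE 0.40) and miR-532-3p at 0.85 (SE 0.40) were not past the threshold.

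Neighbouring miRNA genes changed alike, a pattern that may come from shared transcription. Over 46 pairs of kept miRNAs from genes within 10 kb (160 genes matched by name in the assembly GRCr8), the mean absolute difference of log2 fold changes between neighbours was 0.49 for isografts against normal corneas, 0.57 for allografts against normal corneas and 0.54 for allografts against isografts. Shuffled positions gave 1.19, 1.94 and 1.24 (p = 1e-05 each, the smallest that 100000 permutations can give). Many of the pairs lie in the Dlk1-Dio3 cluster, so the pairs do not stand for as many separate loci. Simulated independent changes passed this test in 2.5% of 200 runs and changes shared within clusters in 89.5%. Pairs that parted stood out: miR-99b-5p, let-7e-5p and miR-125a-5p, from 1 cluster, differed in allografts from normal corneas by 0.07, -0.73 and -1.61, and miR-503-5p and miR-351-5p, from another, by 2.21 and 0.70.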
